A study of Mus musculus with 6 samples.

How the data were processed

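The series measured polyadenylated RNA of eosinophils taken from the small intestinal lamina propria of BALB/c mice, wild type, and kept in culture for 4 hours. There were 3 cultures without added cytokine and 3 with GM-CSF at 10 ng/ml. RNA was extracted with Trizol and made into libraries with the Illumina TruSeq Stranded mRNA kit, per the labels' protocols. How the eosinophils were isolated is not given in the sources used here. Nothing in the labels says whether the cultures of a group came from separate animals, so p-values measure only the spread between these cultures.

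The submitters' processing notes name bcl2fastq 1.8.4, TopHat, TopHat2, Cufflinks and the mouse build mm10, without their order or settings. Each library has 1 table of 30374 RefSeq transcripts, and per the file headers each row holds an FPKM value, a confidence interval, a coverage and a transcript length. The authors deposited FPKM, which is a count of fragments scaled by transcript length and by the mapped fragments of the library, and this is the unit analysed. The deposited coverage was used only to learn the depth. The files hold no read counts, so no count test was used. How reads that fit several transcripts or gene copies were divided is not given in the sources used here, and between 11.3% and 15.7% of transcripts with an FPKM of at least 0.1 lay outside their own deposited interval. The deposited intervals were not used here.

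Coverage divided by FPKM is the same number for all transcripts of a library and equals the mapped bases behind the values, in gigabases. It was 0.939, 0.974 and 0.917 in untreated replicates 1 to 3 and 0.890, 1.32 and 0.820 in GM-CSF replicates 1 to 3. Among the lowest transcripts, coverage times length had a median near 40 nt within a fixed window around that value. This is taken as the length of 1 read. The window itself favours such a median, so the read numbers that follow are approximate. On a transcript of 2000 nt, 1 read was then worth between 0.0151 and 0.0243 FPKM, so such a gene at 1 FPKM rested on between 41.1 and 66.0 reads. Precision is lower for short genes: 833 transcripts were under 200 nt, and tested genes of that length had a median SE of 1.55 on the log2 scale against 0.08 for the others.

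Transcript FPKM were summed per gene symbol and locus, which gave 23664 genes from 23283 symbols (219 symbols were placed at more than 1 locus). The 10136 genes with a mean of at least 1 FPKM over the 6 libraries were tested on log2(FPKM + 1), so every log2 fold change is on that scale, which understates the change of low genes. Fold values in FPKM are ratios of group means. The test was limma 3.58.1 in R 4.3.3 (linear model, empirical Bayes with a trend, two-sided) with Benjamini-Hochberg adjustment and a threshold of 0.05. On simulated log values for the same 10136 genes, with the spread of the GM-CSF comparison, the test recovered 97.5% of genes raised by 1, 97.5% of those raised by 2 and 95.0% of those lowered by 1 on the log2 scale. It recovered 24 of 40 genes raised by 0.5 and 23 of 40 lowered by 0.5, and 2.13% of its calls fell on unchanged genes. The simulation changed 200 genes and 3 lists of 15 genes, while 2208 genes passed in the data. With fewer changed genes the adjusted threshold is stricter, so these rates do not give the sensitivity of the real comparison.

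Before the data were examined, 35 gene lists with 562 entries were fixed from textbook knowledge, 9 of them markers of other cell types. Of the entries, 547 matched a symbol in the files, 11 matched an older symbol or a RefSeq synonym and 4 were not matched. The 30 lists with at least 5 tested members were compared with limma's camera, which asks whether a list's genes moved relative to the other genes, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the lists. In the simulation camera called 3 of 3 lists shifted by 0.4 on the log2 scale and 0 of 27 lists that were not shifted. The simulated genes varied independently of each other. The simulation therefore cannot show how often camera calls unshifted lists whose genes vary together. The estimated correlation, and limma's fry, which asks whether a list's genes move one way on balance, were alternatives.

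Genes named in the text were chosen by a rule fixed before the data were examined. It takes the 10 largest rises and 10 largest falls by log2 fold change among genes that pass the threshold with non-overlapping groups, passing over predicted genes, Rik clones, microRNA and small nucleolar RNA genes (1 entry was passed over among the rises and 2 among the falls). It also takes up to 3 members of each list with the largest change past the threshold, or the 2 most abundant members where none passed. Finally it always takes Il1rn, Il1b, Cish, Csf2ra, Csf2rb, Csf2rb2, Il5ra, Siglecf (listed as Siglec5), Ccr3, Epx and Prg2. Other names are said to have been chosen after their values were seen. A few genes that the rule takes are not reported here. Genes detected per library and the share of FPKM in the 10 highest genes were compared with exact permutation tests, which with 3 libraries against 3 cannot give a p below 0.1.

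Positions come from RefSeq on GRCm38.p6, the assembly that mm10 is built on, matched by transcript accession. No 2 libraries held duplicate values: at most 0.641% of the tested genes had identical values in any pair, and in that pair all of them were listed at 0 in both libraries. Alternatives covered the pseudocount, the filter on low values, 3 other scalings of the libraries, the variance model, library weights, transcripts in place of gene sums, the replicate number as a block, and each library left out in turn. One alternative, the tested genes restricted to those with a transcript of at least 200 nt, was chosen after seeing the data. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.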

Results

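Eosinophils are granulocytes that reside in the small intestinal lamina propria in healthy mice, and GM-CSF is a cytokine that acts on them through a receptor made of Csf2ra and the shared beta chain Csf2rb. The series asked which genes change when these cells are cultured with GM-CSF for 4 hours. The 6 libraries, 3 untreated and 3 with GM-CSF, rested on between 0.820 and 1.32 gigabases of mapped sequence each. The first principal component of the log values held 33.1% of the variance and separated the groups. Genes detected at 1 FPKM or more numbered 10112 ± 43.3 (SD, n = 3) in untreated and 9933 ± 52.0 (SD, n = 3) in GM-CSF libraries, without overlap (exact two-sided permutation test, p = 0.1, the smallest it can give). The 10 highest genes took 13.9% ± 2.15 (SD, n = 3) of the FPKM in untreated and 13.3% ± 1.18 (SD, n = 3) in GM-CSF libraries (exact two-sided permutation test, p = 0.8).

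GM-CSF raised some genes and lowered others. Car4, a carbonic anhydrase (chromosome 11, 84957754 to 84966054, GRCm38), rose from 0.997 ± 0.0680 to 67.8 ± 5.15 FPKM (SD, n = 3 each; log2 fold change 5.10, SE 0.07, limma adjusted p = 9.58e-07). The feedback inhibitors of cytokine signalling rose with it. Socs1 went from 3.77 to 88.6 FPKM (log2 fold change 4.24, SE 0.21), Socs3 from 4.01 to 45.7 (3.22, SE 0.06) and Cish (chromosome 9, 107296659 to 107302784) from 17.9 to 156.7 (3.07, SE 0.10). The other 6 of the 10 largest rises were the activating receptor gene Tarm1 (4.04), the transglutaminase gene Tgm1 (3.96), the leukotriene B4 receptor gene Ltb4r2 (3.33), the prolyl hydroxylase gene Egln3 (3.11), the kinase gene Pim2 (2.94) and the growth factor gene Hbegf (2.92), all on the log2 scale.

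Apart from the short RNA gene Scarna2, described below, the largest falls were smaller. The transcriptional repressor gene Bcl6 (chromosome 16, 23965050 to 23988866) went from 6.89 ± 1.16 to 1.35 ± 0.573 FPKM (SD, n = 3 each; log2 fold change -1.77, SE 0.19, limma adjusted p = 0.00132). The 12/15-lipoxygenase gene Alox15 (chromosome 11, 70344147 to 70390538) went from 460.6 ± 41.0 to 157.0 ± 9.26 FPKM (log2 fold change -1.54, SE 0.08, limma adjusted p = 5.27e-05). The gut-homing integrin gene Itgb7 fell by 1.57 and the surface antigen gene Cd52 by 1.33 on the log2 scale. Others among the 10 were Alox12e (-1.43), Dio2 (-1.37), Glod5 (-1.35) and the small nuclear RNA gene Scarna2. Scarna2, of 61 nt, was listed at 0 in all 3 GM-CSF libraries and at 377.9, 364.4 and 129.1 FPKM in the untreated ones (SE 0.40 on the log2 scale, limma adjusted p = 5.27e-05). It passed under all 18 alternatives in which it was tested. The alternative restricted to genes with a transcript of at least 200 nt leaves it out. Tested genes under 200 nt had a median SE of 1.55, so this fall is less secure than those of longer genes.

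Across the 10136 genes tested, 2208 changed (limma, adjusted p under 0.05), 771 up and 1437 down. All 2208 had non-overlapping groups, as did 39.1% of all tested genes, where chance gives 10%. A log2 change of at least 1 was reached by 147 rises and 33 falls. The excess of falls depended on the scaling: median-of-ratios factors gave 995 up and 1054 down, and quantile normalization 943 and 1114. Rescaling each library to the same sum gave 804 and 939, but it also raised all values against the fixed filter and pseudocount, so that 11283 genes were tested. The median log2 fold change of all genes was -0.05 as deposited. Among the genes named here, the calls of Lyz2, Gzma, Igj, Zbp1, Cxcl3, Gata2, Epx, Mzb1, Trp53inp1, Krt8 and Irf7 ended under at least 7 of the alternatives run.

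**Figure D1:**
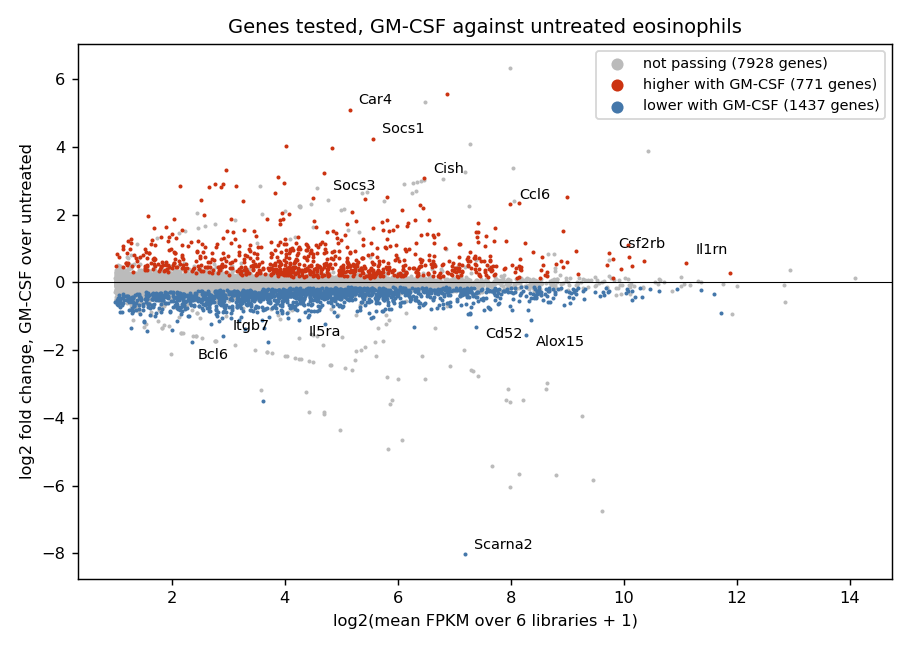
Log2 fold change (GM-CSF over untreated, vertical axis) against log2(mean FPKM + 1) over the 6 libraries (horizontal axis), 1 point per tested gene, coloured by whether it passed the limma threshold. The 771 rises reach larger values than the 1437 falls, apart from Scarna2 and the 164 nt small nucleolar RNA gene Snora81, and many short RNAs with large values did not pass.

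**Figure D2:**
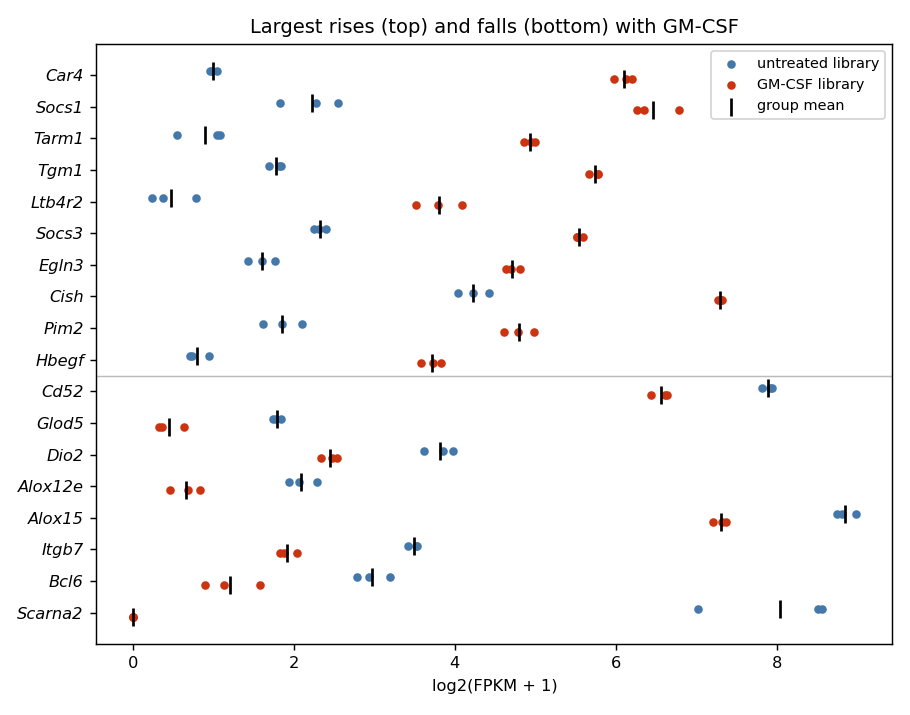
Log2(FPKM + 1) of the 10 largest rises and 8 of the 10 largest falls, with 1 point per library and a bar at each group mean (3 untreated and 3 GM-CSF libraries). No gene shown has overlapping groups.

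Targets of STAT5, the transcription factor that GM-CSF receptors activate, rose as a list with the preset correlation. Of 14 tested STAT5 target and feedback genes, 10 rose, 1 fell and 3 did not pass (11 up and 1 down adjusted over the list alone; camera adjusted p = 2.33e-10, adjusted p = 0.142 with an estimated correlation). Socs1, Socs3 and Cish led the list and Bcl6, which STAT5 is known to repress, was the member that fell. Among receptor and signalling genes, 3 of 13 rose and 5 fell (the same counts adjusted over the list alone), and the list did not move one way (camera adjusted p = 0.942). The beta chain gene Csf2rb (chromosome 15, 78325800 to 78351001) rose from 600.4 ± 34.0 to 1098 ± 23.7 FPKM (log2 fold change 0.87, SE 0.05) and its neighbouring near copy Csf2rb2 from 234.2 to 432.9 (0.88, SE 0.05), and reads of this pair may have been divided with error. Jak2, the receptor's kinase, rose by 1.08. Csf2ra measured 332.6 and 324.3 FPKM (log2 fold change -0.04, adjusted p = 0.768). The IL-5 receptor gene Il5ra (chromosome 6, 106710375 to 106749037) fell from 25.1 to 11.2 FPKM (log2 fold change -1.10, SE 0.11).

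Genes of the IL-1 family rose as a list with the preset correlation, though not every member did. Il1rn, which encodes the IL-1 receptor antagonist (chromosome 2, 24336860 to 24351491), was already abundant and went from 1769 ± 79.0 to 2631 ± 8.63 FPKM (SD, n = 3 each; log2 fold change 0.57, SE 0.05, limma adjusted p = 0.000378). Il1b rose from 948.4 to 1317 FPKM (0.47, SE 0.06). Il18rap (1.10) and Il1rl1, the IL-33 receptor gene (0.76), rose from low levels. In all, 6 of 12 members rose, 1 fell and 5 did not pass (6 and 1 adjusted over the list alone; camera adjusted p = 0.000613, adjusted p = 0.142 with an estimated correlation). The 3 transcripts of Il1rn differ in whether the protein is secreted, but their shares of the gene's FPKM ranged from 18.8% to 43.4% for 1 of them across the 6 libraries, so only the gene sum is read here.

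Genes that restrain apoptosis rose as a list with the preset correlation. Of 10 pro-survival genes, 6 rose, 2 fell and 2 did not pass (6 and 2 adjusted over the list alone; camera adjusted p = 0.000611, adjusted p = 0.257 with an estimated correlation). Bcl2l1 (chromosome 2, 152758732 to 152833803), which encodes Bcl-xL, went from 5.01 to 23.9 FPKM (log2 fold change 2.05, SE 0.08). Bcl2a1a rose from 86.6 to 246.0 FPKM and Bcl2a1d by 1.34 on the log2 scale, although members of this near-identical family may share reads. Of 16 pro-apoptotic genes, 1 rose, 6 fell and 9 did not pass (1 and 6 adjusted over the list alone; camera adjusted p = 0.167, while fry called the list down, adjusted p = 0.00523). The difference between these lists was not tested. Bmf (-0.66) and Trp53inp1 (-0.58) were among those that fell.

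Cholesterol synthesis genes rose as a list by modest amounts with the preset correlation. Of 22, 11 rose, 0 fell and 11 did not pass (17 up adjusted over the list alone; median log2 fold change 0.27; camera adjusted p = 1.57e-08, adjusted p = 0.125 with an estimated correlation). Acat2 rose by 0.48, Fdps by 0.47 and Stard4 by 0.43. Of 13 amino acid response genes, 4 rose and 1 fell (6 and 2 adjusted over the list alone; camera adjusted p = 0.0170, adjusted p = 0.361 with an estimated correlation), with Aldh18a1 (0.65), the transporter gene Slc7a5 (0.51) and Mthfd2 (0.45) in front. This call ended with median-of-ratios factors (adjusted p = 0.0530), after rescaling to one sum (0.103), where more genes and lists were tested, without untreated replicate 3 (0.0834) and without GM-CSF replicate 3 (0.0527). Of 7 ERK feedback genes, 4 rose and 1 fell (4 and 1 adjusted over the list alone; camera adjusted p = 0.0447, adjusted p = 0.272 with an estimated correlation), among them Spred1 (1.21), Etv5 (1.17) and Spred2 (0.46). That call ended under 9 alternatives, among them without untreated replicate 3 (adjusted p = 0.0858), GM-CSF replicate 1 (0.0684) or GM-CSF replicate 3 (0.0621). With an estimated correlation 0 of the 30 lists passed, against 9 with the preset one. The estimate was below the preset 0.01 for IL-1 family (-0.034), ERK feedback (-0.085), T cell (0.0027) and B and plasma cell (-0.051) lists. Genes that vary together therefore do not account for the loss of these calls. For cholesterol synthesis genes, at 0.014, camera p went from 1.05e-09 to 0.00416 before adjustment. For the other passing lists the estimate was between 0.111 and 0.170, and there this stays open. What else ended the calls was not tested.

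Markers of B and plasma cells, T cells and epithelial cells fell as lists with the preset correlation, and the other marker lists did not pass or were too short to test. All 6 tested B and plasma cell markers fell (6 down adjusted over the list alone; camera adjusted p = 0.00482, adjusted p = 0.198 with an estimated correlation). Igj fell by 0.88, Cd79b by 0.88 and Mzb1 by 0.81. Of 6 T cell markers, 4 fell and 2 did not pass (4 down adjusted over the list alone; camera adjusted p = 0.00953, adjusted p = 0.205 with an estimated correlation), led by Lck (-0.96), Cd3e (-0.75) and Cd3g (-0.65). Of 13 epithelial markers, 6 fell and 7 did not pass (8 down adjusted over the list alone; camera adjusted p = 0.0170, adjusted p = 0.361 with an estimated correlation). Krt19 (-0.81), Lyz1 (-0.69) and Krt8 (-0.68) fell. Of 6 macrophage and dendritic cell markers, 3 fell, Csf1r (-0.86), Apoe (-0.63) and Lyz2 (-0.42) (4 adjusted over the list alone; camera adjusted p = 0.330). Of 7 neutrophil markers, Cxcr2 rose (2.15) and S100a8 (-0.77) and Retnlg (-0.43) fell (1 up and 4 down adjusted over the list alone; camera adjusted p = 0.330). Retnlg measured 1344 and 998.6 FPKM in untreated and GM-CSF libraries, S100a8 15.1 and 8.48. Fewer than 5 markers were tested for 4 other types, which were not compared as lists. Kit (-0.75) and Gata2 (-0.33) fell among 4 mast cell markers, Il7r (-0.71) and Gzma (-0.43) among 4 innate lymphoid and NK cell markers. Of 3 stromal and endothelial markers Pdgfra rose (1.04) and Pecam1 fell (-0.41, from 154.8 to 116.5 FPKM). Whether RNA of abundant markers such as Retnlg and Pecam1 came from other cells or from the eosinophils was not tested. Beta-s, a haemoglobin gene of a near-identical family, was the only erythroid marker tested (0.72, adjusted p = 0.561), and Hbb-b1 averaged 0.508 FPKM.

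**Figure D3:**
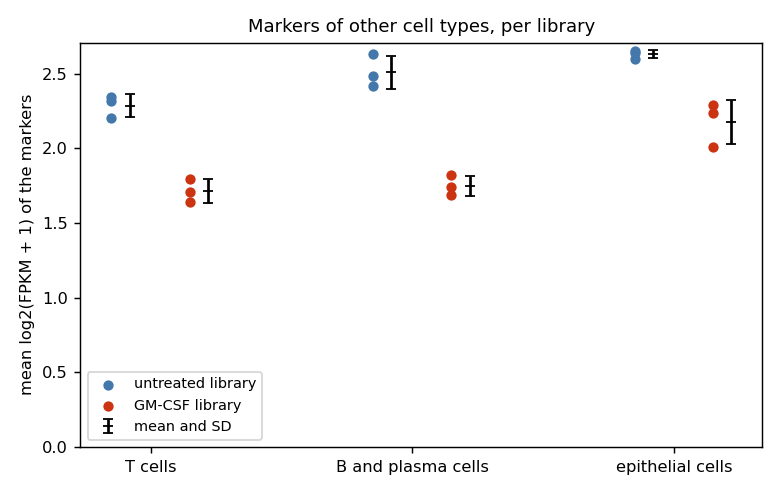
Mean log2(FPKM + 1) of the tested markers of T cells (6 genes), B and plasma cells (6 genes) and epithelial cells (13 genes) in each library, with the mean and SD of each group of 3. The GM-CSF libraries lie below the untreated ones for each of these types.

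Genes that define eosinophils went both ways. Siglec5, the files' symbol for Siglecf (chromosome 7, 43351341 to 43359475), measured 170.1 and 170.4 FPKM (log2 fold change 0.00, adjusted p = 0.978). Ccr3 measured 289.0 and 251.3 FPKM (log2 fold change -0.20, adjusted p = 0.152) and the granule protein gene Prg2 8.85 and 8.93 FPKM (0.02, adjusted p = 0.917). Alox15, Il5ra and Cebpe (-0.60) fell, and the peroxidase gene Epx fell from 6.62 to 4.27 FPKM (-0.54, adjusted p = 0.0375). Of the 13 members tested, 2 rose, 5 fell and 6 did not pass (2 and 5 adjusted over the list alone; camera adjusted p = 0.658).

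Secreted mediators and surface receptors changed gene by gene. Ccl6, a CC chemokine gene, rose from 84.1 to 419.5 FPKM (log2 fold change 2.31, SE 0.09) and Cxcl3 rose by 0.40, while Ccl5 fell by 0.66. Of 10 chemokine genes, 2 rose and 1 fell (2 and 1 adjusted over the list alone; camera adjusted p = 0.566). Of 14 other cytokine genes, 4 rose and 2 fell (5 and 2 adjusted over the list alone; camera adjusted p = 0.0668). Hbegf (2.92), Il27 (1.34) and Tgfb1 (1.07), which went from 119.3 to 252.0 FPKM, rose. Tgfb1 and Ltb (0.39) were the 2 IgA support genes abundant enough to be tested, and both rose. Of 20 adhesion and migration genes, 5 rose and 7 fell (5 and 11 adjusted over the list alone; camera adjusted p = 0.940). The chemokine receptor gene Cxcr2 went from 23.8 to 109.3 FPKM (2.15, SE 0.06), while Itgb7 and Cxcr4 (-0.66) fell. Of 12 lipid mediator genes, 5 rose and 4 fell (5 and 4 adjusted over the list alone; camera adjusted p = 0.330), with Pla2g4a (0.93) and the prostaglandin receptor gene Ptger2 (0.91) up and Alox15 down.

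Of 11 antigen presentation and co-stimulation genes, 3 rose and 5 fell (4 and 7 adjusted over the list alone; camera adjusted p = 0.790). The co-stimulatory ligand genes Cd80 (1.17, from 186.8 to 420.9 FPKM) and Icosl (0.67) rose. The MHC class II gene H2-Ab1 fell from 18.9 to 10.1 FPKM (-0.84, SE 0.05), a fall measured beside that of the B cell markers above. Of 15 matrix and coagulation genes, 4 rose and 6 fell (4 and 7 adjusted over the list alone; camera adjusted p = 0.929), including Mmp25 (0.68), Mmp9 (-0.80) and Mmp13 (-0.88). Of 6 alternative activation genes, 3 rose and 2 fell (4 and 2 adjusted over the list alone; camera adjusted p = 0.0668), with Il4ra (1.05) and Egr2 (0.56) up and Retnla (-0.56) down. Of 16 NADPH oxidase and redox genes, 5 rose and 4 fell (5 and 4 adjusted over the list alone; camera adjusted p = 0.849). The oxidase subunit genes Cybb (-1.04) and Ncf4 (-0.82) fell and Gclm, a glutathione synthesis gene, rose (0.70).

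**Figure D4:**
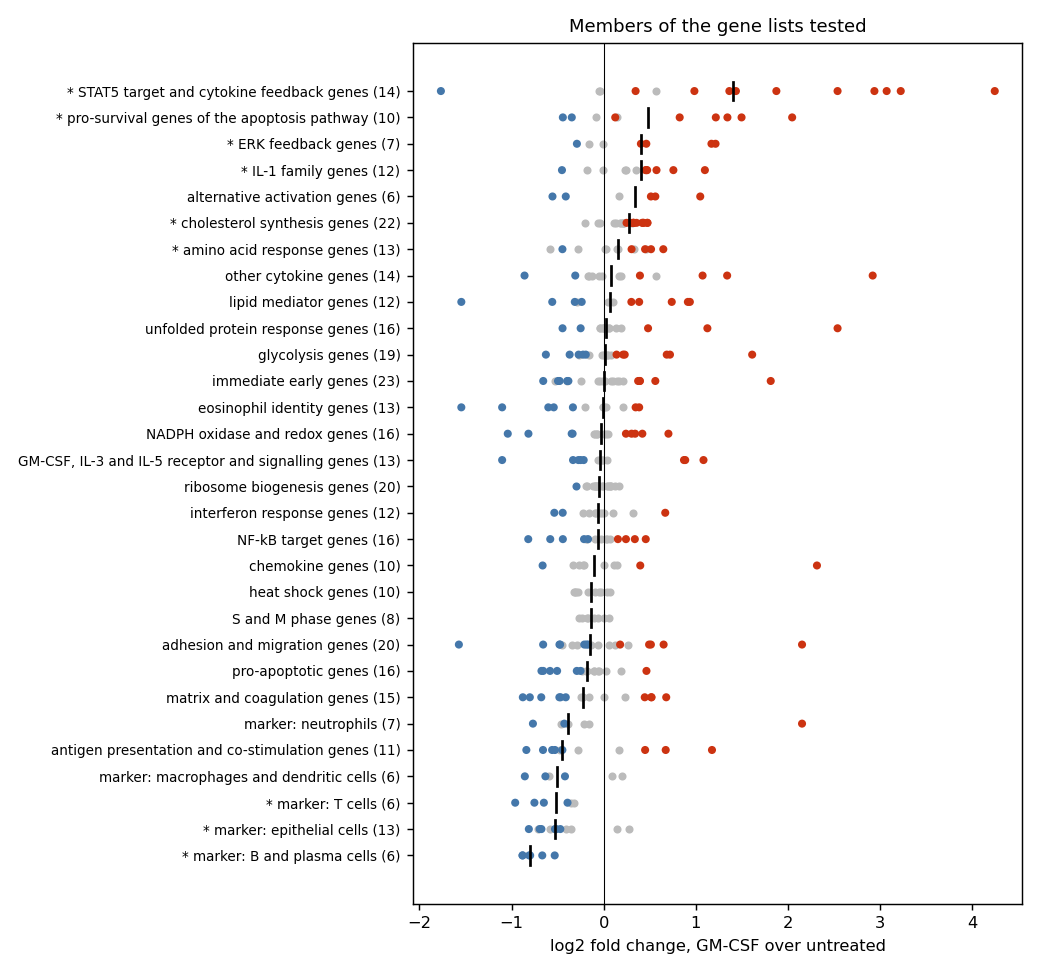
Log2 fold change (GM-CSF over untreated, horizontal axis) of each tested member of the 30 lists, ordered by median (black bar), with the number of members in brackets. Red and blue points passed the limma threshold, grey points did not, and a star marks the 9 lists that passed camera with the preset correlation.

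The remaining lists did not pass camera. Of 16 unfolded protein response genes, 3 rose and 2 fell (3 and 2 adjusted over the list alone; camera adjusted p = 0.0668), and Xbp1 went from 15.4 to 94.0 FPKM (2.54, SE 0.08), with Pdia4 (1.13) and Manf (0.48) also up. Of 19 glycolysis genes, 6 rose and 5 fell (6 and 5 adjusted over the list alone; camera adjusted p = 0.332), among them Eno1 (1.61), which has near-identical copies, Slc2a1 (0.72) and Pfkp (0.68). Of 16 NF-kB target genes, 4 rose and 5 fell (4 and 6 adjusted over the list alone; camera adjusted p = 0.973), among them Traf1 (-0.82), Tnip1 (-0.58) and Nfkb1 (0.46). Of 23 immediate early genes, 5 rose and 5 fell (6 and 5 adjusted over the list alone; camera adjusted p = 0.189), among them Ier3 (1.81), Fosb (-0.66) and Egr2 (0.56). Of 12 interferon response genes, 1 rose and 2 fell (1 and 2 adjusted over the list alone; camera adjusted p = 0.940): Zbp1 (0.67), Irf7 (-0.54) and Oasl1 (-0.44). Of 20 ribosome biogenesis genes, Pes1 alone changed (-0.30; 1 down adjusted over the list alone; camera adjusted p = 0.992). None of 10 heat shock genes (camera adjusted p = 0.330) and none of 8 S and M phase genes (camera adjusted p = 0.452) passed, either over all genes or adjusted over the list alone. The most abundant of these were Hspa8 at 1132 and 1105 FPKM, Hsp90ab1 at 665.3 and 697.2, Pcna at 87.7 and 77.8 and Mcm4 at 9.62 and 8.88, in untreated and GM-CSF libraries.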

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

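The number of changed genes stayed within 1.5 times of 2208 under every alternative run, from 1515 to 2459, the latter with genes that have a transcript of at least 200 nt only, an alternative chosen after seeing the data. Leaving out 1 library gave between 1515 and 1786 changed genes. Between 58.7% and 63.2% of these fell, against 65.1% with all libraries. The lowest count, without untreated replicate 2, held 626 rises and 889 falls. Single transcripts gave 1531. No changed gene took the opposite sign under any alternative fitted to gene sums, while 25 did when the highest transcript stood for its gene. Of 9 lists passing camera, 5 had enough members to be tested at a mean of at least 5 FPKM, and all 5 passed. With the estimated correlation 0 passed, as described above. Fry called 19 lists, with ribosome biogenesis genes (adjusted p = 0.0280) and neutrophil markers (adjusted p = 0.00669) on the other side from camera, where neither passed. The 2 tests ask different questions, so this is no change of direction. Leaving out 1 library gave between 8 and 11 lists. The difference in detected genes kept its sign at cutoffs of 0.1 and 5 FPKM and with each library left out. It was not recomputed under the other scalings of the libraries. The difference in the share of the 10 highest genes (-0.655 percentage points) turned to 0.540 without untreated replicate 2 and to 0.00555 without GM-CSF replicate 2, and ran from -1.54 to 0.540 over the libraries left out; the cause was not tested. Same-numbered libraries were not taken as pairs: over all genes their deviations correlated at -0.03, 0.05 and -0.02, and 2 of 6 libraries correlated best with their own number. These figures over all genes do not exclude an effect shared by same-numbered libraries in some genes. Replicate 3 was low in both groups for several gene lists, as described below. With the replicate block 1990 genes and 8 lists passed; ERK feedback genes did not (adjusted p = 0.114), and Ccr3 gained a call (-0.20, adjusted p = 0.0190). Other lists gained a call when 1 library was left out: other cytokine genes without untreated replicate 1 (0.0493) or GM-CSF replicate 3 (0.0376), unfolded protein response genes without untreated replicate 1 (0.0493), heat shock genes without untreated replicate 3 (0.0405), and immediate early (0.0141) and alternative activation genes (0.0456) without GM-CSF replicate 3. Heat shock and immediate early genes were often lowest in replicate 3 of both groups, as described below. Leaving it out of 1 group alone unbalances the groups for these genes, and neither list passed with the replicate block. Unfolded protein response genes also passed with median-of-ratios factors (0.0445) and after rescaling to one sum (0.0336), where 31 lists were tested. After that rescaling 10 lists passed, 8 of them among the 9 of the main result. Of 102 named genes that passed, 80 passed under every alternative run and 22 lost the call under at least 1. Lyz2 lost it under 13, and Gzma, Igj and Zbp1 under 11. Fosb lost it under 5, Mmp13 under 3 and Ccl5 under 2, in each case also when single libraries were left out. Of 9 that did not pass, 2 gained a call, Ccr3 as above and Pcna without GM-CSF replicate 3 (-0.24, adjusted p = 0.0325). Of simulated changes of 0.5 on the log2 scale, with the spread of this comparison, 24 of 40 rises and 23 of 40 falls were called. Far fewer genes were changed in the simulation than passed in the data, so these rates do not give the sensitivity of the real comparison.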

Other observations

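The gene families and all tests of explanations below were chosen after the results were seen, except the counts over other splits of the libraries. The ribosomal protein family was first taken by a wider symbol prefix and then narrowed, after its values were seen, to leave out kinase genes and pseudogenes. Under the wider prefix 51 of 91 genes fell and 1 rose. Genes for cytosolic ribosomal proteins fell together by small amounts. Of 74 tested, 49 fell, 0 rose and 25 did not pass, with a median log2 fold change of -0.24 (camera adjusted p = 1.66e-13 over 41 families named by symbol, adjusted p = 0.837 with an estimated correlation). Rpl12 went from 390.8 to 284.1 FPKM, Rps24 from 401.0 to 292.7 and Rps27a from 602.2 to 444.2. The paired immunoglobulin-like receptors of the Lilr, Pir and Gp49 families went the other way: 3 of 8 rose and 0 fell (camera adjusted p = 0.00659, adjusted p = 0.941 with an estimated correlation). Lilrb4 rose from 813.2 to 1376 FPKM and Gp49a from 1020 to 1589. These genes have similar sequences, and how their reads were divided was not tested.

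The fall of ribosomal protein genes was weighed against technical explanations. Their transcripts are short, but 0 of 10000 random lists matched on transcript length and mean FPKM had a median as low, and the lowest reached -0.19. The lists were drawn gene by gene, so they do not show how far genes that vary together can move. How closely the drawn genes matched was not tested. With median-of-ratios factors the median of the ribosomal protein genes went from -0.24 to -0.18. The scaling of the libraries can thus account for part of the fall but not for all of it. How many of these genes pass with those factors was not counted. Reads shared with the many processed pseudogenes of these genes were not tested. Nor was less RNA from other cells, whose markers fell in the same GM-CSF libraries. Both stay open, and so does a change in the eosinophils with GM-CSF as an untested hypothesis.

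For the joint fall of T cell, B cell and epithelial markers, the highest of the 3 list medians was still -0.47 with median-of-ratios factors, which argues against scaling. Their mean log2 changes were -0.57 (SE 0.06) for T cells, -0.76 (SE 0.07) for B and plasma cells and -0.45 (SE 0.09) for epithelial cells. A smaller amount of RNA from other cells would lower all of them alike, and the largest difference between lists, 0.31 between B cell and epithelial markers, was 2.32 standard errors, over the bound of 2 set for this test. That argues against an equal loss only weakly, with 3 libraries a group and a log scale that compresses low genes. The pair was also taken as the largest of 3, so an equal loss is not excluded. Unequal losses of each cell type, and a change in eosinophils that express some of these genes, stay open, and how the cells were isolated is not given in the sources used here.

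The excess of falls over rises (1437 against 771) could be due to the scaling of the libraries. A small common shift would add falls only among small changes, and among the 805 changed genes with a log2 change of at least 0.5 either way 51.3% fell, 413 against 392. Less RNA from other cells would leave abundant genes balanced. Of 1129 changed genes with a mean of at least 20 FPKM 62.8% fell as deposited, but 48.4% of 1020 with median-of-ratios factors, so the scaling can tilt these genes too and this explanation stays open. A real majority of small falls with GM-CSF was not tested and stays open.

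The 6 libraries can be split 3 against 3 in 10 ways, too few for a share under 0.05. The real split was the 1 with the most changed genes, 2208, and the highest of the others gave 5. Each other split mixes GM-CSF and untreated libraries in both groups. A treatment difference then adds to the spread within groups and lowers the count, so these counts do not measure chance alone. For gene lists it was again the 1 with the most, 9, but the highest of the others gave 7.

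Replicate 3 was low in several gene lists in both groups. It was the lowest of its group in both groups for 9 of 10 heat shock genes, 11 of 23 immediate early genes and 5 of 10 chemokine genes, against 9.97% of all tested genes. Fos measured 216.9, 219.7 and 182.1 FPKM in untreated and 166.7, 151.1 and 122.2 FPKM in GM-CSF replicates 1, 2 and 3. The cause was not tested. The shares of transcripts within genes were also compared: 0 of 1984 transcripts passed limma's diffSplice test after adjustment, and 267 had an unadjusted p under 0.05. These are more than the share of 0.05 that chance gives, so changes of transcript share are not excluded.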
